A study of Mus musculus with 16 samples.

How the data were processed

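Single J1 mouse embryonic stem cells and 20 pg aliquots of pooled total RNA were profiled with CEL-seq in 2i medium (1 uM PD0325901, 3 uM CHIR99021 and 1000 units of LIF per ml, on gelatin) and in serum medium (15% fetal calf serum and 1000 units of LIF per ml, on embryonic fibroblasts), per the labels' protocols. Cells were dissociated, picked one by one with a glass capillary and lysed with 0.05% IGEPAL in the reverse transcription mix. A UMI of 4 random bases was placed between the cell barcode and the poly-T primer, and 50 bp paired reads were sequenced from 2 libraries on 2 lanes per group. GEO lists 16 samples, 1 for each library and lane of the 4 groups. Reads were aligned with BWA 0.6.2 and the genome build was mm10, per the submitters' processing notes; the annotation, the treatment of reads that match several genes and any filter on genes are not given in the sources used here.

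The deposited table holds expected counts, that is estimated transcript numbers that need not be whole, for 12485 genes and 50 ERCC spike-ins in 320 columns, 80 for each group. Its values were checked against the UMI length. With 256 possible UMIs, 86.2% of the values above 0 equal 256 times the negative natural logarithm of (1 - k/256) for a whole number k of UMIs, within a tolerance of 1e-06, so the authors converted UMI numbers to transcript numbers with a correction for repeated use of a UMI. The other values correspond to fractions of a UMI. In 2282 genes more than 10% of the values above 0 were of that kind, and in 1240 genes more than 50%. Sharing of reads between genes would give such values, but how they arose was not tested. These genes are called uncertain, and the other 10203 genes are described as having whole UMI numbers. Genes over 50% took 37.7% of the transcripts of 2i cells, 48.9% of serum cells, 35.7% of 2i aliquots and 30.3% of serum aliquots, so that shares of all transcripts are not comparable between groups without regard to the median gene. A total of 931 genes were at 0 in every 2i column and 745 in every serum column, always in cells and aliquots together. Every other gene had a value in at least 2 cells and at least 2 aliquots of the medium. Such genes are described as listed at 0 and get no ratio, which departs from the written rule that would have ranked them.

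The columns carry the group and a running number but no library or lane, so each group was treated as 1 pooled sample, and all columns were matched to a group. Cells and aliquots are not replicates. No test was run, no p-value is given, and every group difference is a comparison of pooled samples. Before the data were examined, a column was to be kept when its total of endogenous transcripts was at least the group's median divided by 3, which left out 6 cells in 2i, 25 cells in serum, 4 aliquots in 2i and 24 aliquots in serum. In serum 22 of these lay in columns 41 to 80 of each material. Cells had been picked by hand, no doublet caller was run and no upper limit was set. The highest total was 120306 in 2i cells and 129078 in serum cells.

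Culture ratios are log2 of the share of all endogenous transcripts in 2i over that in serum, from counts rounded to whole numbers and summed over the kept columns (3880418 transcripts in 2i cells, 3442538 in serum cells, 6115765 in 2i aliquots and 5848248 in serum aliquots). Their 95% intervals are exact, from the binomial distribution of the summed counts given their total, and cover counting error only. A gene needed at least 50 summed transcripts in the higher medium in both materials. Noise was measured after thinning each column at random without replacement to 33763 transcripts, the 10th percentile of the kept totals, which kept 57 cells and 75 aliquots in 2i and 46 cells and 56 aliquots in serum. The excess is CV2 over cells minus CV2 over aliquots, for genes with a thinned mean of at least 2 transcripts in both. The means of cells and aliquots were not matched, so a gap between them adds counting noise to the excess or takes it away. Lists were placed by the percentile of their median among 10000 random lists of the same size matched on mean expression, as a description of these pooled samples. A percentile is given only for 3 or more measured members. The list of mitochondrially encoded genes had no member in the table, and the list of cleavage-stage (2-cell-like) genes had 5, none with a ratio. The computation was tested on simulated data with the real genes and totals and with means pooled over all kept columns. It recovered a median excess of 0.476 in 2i and 0.494 in serum for 200 genes simulated at 0.5, and log2 ratios relative to the median gene of 2.01 in cells and 2.00 in aliquots for 100 genes raised by 2. Apart from the simulated changes, all 4 groups shared these means, and Poisson counting was the only technical noise. The simulation thus could not show the effect of means that differ between cells and aliquots, of column blocks or of fractional values.

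The genes to be named were fixed by rule before the data were examined. For the culture ratio they were the 8 genes in each direction with the largest value of the smaller of the 2 absolute log2 ratios, up to 4 members of each list that were at least 2-fold apart in both materials, and 6 pluripotency genes whatever their values. For noise they were the 8 genes with the largest excess in each medium and with the largest difference in each direction, ranked after leaving out the highest column of each gene, and up to 2 members of each list. Because many of these turned out to have fractional values, the top genes with whole UMI numbers were added after the data were seen, as were the genes with the most transcripts among those listed at 0. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 also names. Alternatives chosen in advance were median-of-ratios, TMM and spike-in scaling, equal weights per column, other minimums, all columns, leaving out each gene's highest column, other thinning depths and seeds, scaled and unscaled values, leaving out cells with over 1% fibroblast transcripts, and random lists without matching. Restriction to whole UMI numbers, the 2 column blocks and keeping genes listed at 0 were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, and edgeR 4.0.16 in R 4.3.3 gave the TMM factors.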

Results

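Transcripts were counted in single J1 mouse embryonic stem cells grown in 1 of 2 media, and in aliquots of pooled RNA from the same kinds of culture. The 2i medium is serum-free and holds inhibitors of MEK (PD0325901) and of GSK3 (CHIR99021) together with LIF, a cytokine that sustains self-renewal. The serum medium holds fetal calf serum and LIF, and these cells grew on a layer of mouse embryonic fibroblasts. In the pool-and-split control, RNA from a large number of lysed cells was divided into aliquots of 20 pg. Variation between aliquots is thus technical. The method was CEL-seq, which tags the 3' end of each mRNA with a cell barcode and a short random sequence, the unique molecular identifier (UMI), so that molecules and not amplified copies are counted. The 4 groups were single cells in 2i, single cells in serum, aliquots in 2i and aliquots in serum, with 80 columns each. The column names give no library, so each group was 1 pooled sample and no difference between groups has a replicate check.

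After the filter on totals, 74 cells in 2i, 55 cells in serum, 76 aliquots in 2i and 56 aliquots in serum remained. A 2i cell held a median of 49588 transcripts (range 20680 to 120306) and a serum cell 55194 (13848 to 129078). The aliquots held a median of 76868 in 2i (33764 to 133325) and 103146 in serum (66421 to 176328). The coefficient of variation of the totals was 42.9% over 2i cells and 50.3% over serum cells, against 21.5% and 24.8% over the aliquots. Divided by the ERCC spike-in total of the same column, it was 31.2% over 2i cells, 42.8% over serum cells, 8.67% over 2i aliquots and 13.5% over serum aliquots. Within columns 1 to 40 and columns 41 to 80 it was 33.2% and 29.5% over 2i cells and 47.9% and 32.4% over serum cells. Over the aliquots it was 7.44% and 8.89% in 2i and 9.22% and 9.08% in serum. The median of this ratio was 57.5 over 2i cells and 48.9 over serum cells, but 99.8 over 2i aliquots and 81.3 over serum aliquots. The median number of genes detected per cell was 6615.5 in 2i and 6171 in serum, and 5677 and 4964.5 once each column was thinned to 33763 transcripts. Columns 1 to 40 and columns 41 to 80 of a group differed in depth, with a median of 37656 against 56279 transcripts in 2i cells and 45378 against 79811 in serum cells. They were treated as 2 blocks without a link to the libraries, and values within the blocks are given beside pooled ones for most noise differences and co-variation of gene lists and for some single genes.

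The first comparison asked how the transcriptome of the stem cells differed between the media. By list median, targets of Wnt signalling and genes of sterol and fatty acid synthesis were higher in 2i, and targets of ERK signalling, genes of the primed epiblast and imprinted genes were higher in serum. These medians had the same direction in summed single cells and in summed RNA aliquots, with single members going the other way. Sp5, a transcription factor induced by Wnt signalling, had 557 transcripts in 2i cells and 16 in serum cells, a log2 ratio of 4.95 (95% interval 4.24 to 5.77, exact, counting error only). Dnmt3l, the cofactor of the de novo DNA methyltransferases, had 17 transcripts in 2i cells and 547 in serum cells, a log2 ratio of -5.18 (-5.97 to -4.49). In the aliquots the log2 ratio was 3.63 for Sp5 and -5.53 for Dnmt3l.

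Of 7132 genes with at least 50 summed transcripts in the higher medium in both materials, 268 were at least 2-fold higher in 2i and 132 at least 2-fold higher in serum in both cells and aliquots. In cells alone the counts were 1031 and 196 and in aliquots alone 339 and 464, so the balance between media turned with the material. Scaled to the spike-ins instead, the numbers were 439 and 99. Across genes, which are not independent replicates, the log2 ratios in cells and aliquots had a Pearson r of 0.646 and a Spearman rho of 0.485. Among the 5782 genes whose values were nearly all whole UMI numbers, r was 0.760 and rho 0.647. The ratios are shares of all transcripts, and their median over the eligible genes was 0.29 in cells and -0.16 in aliquots. Median-of-ratios scaling shifted all log2 ratios by -0.30 in cells and by 0.24 in aliquots, and medians of gene lists are given on that scale. Within columns 1 to 40 the count higher in 2i was 113, and within columns 41 to 80 the count higher in serum was 71.

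**Figure D1:**
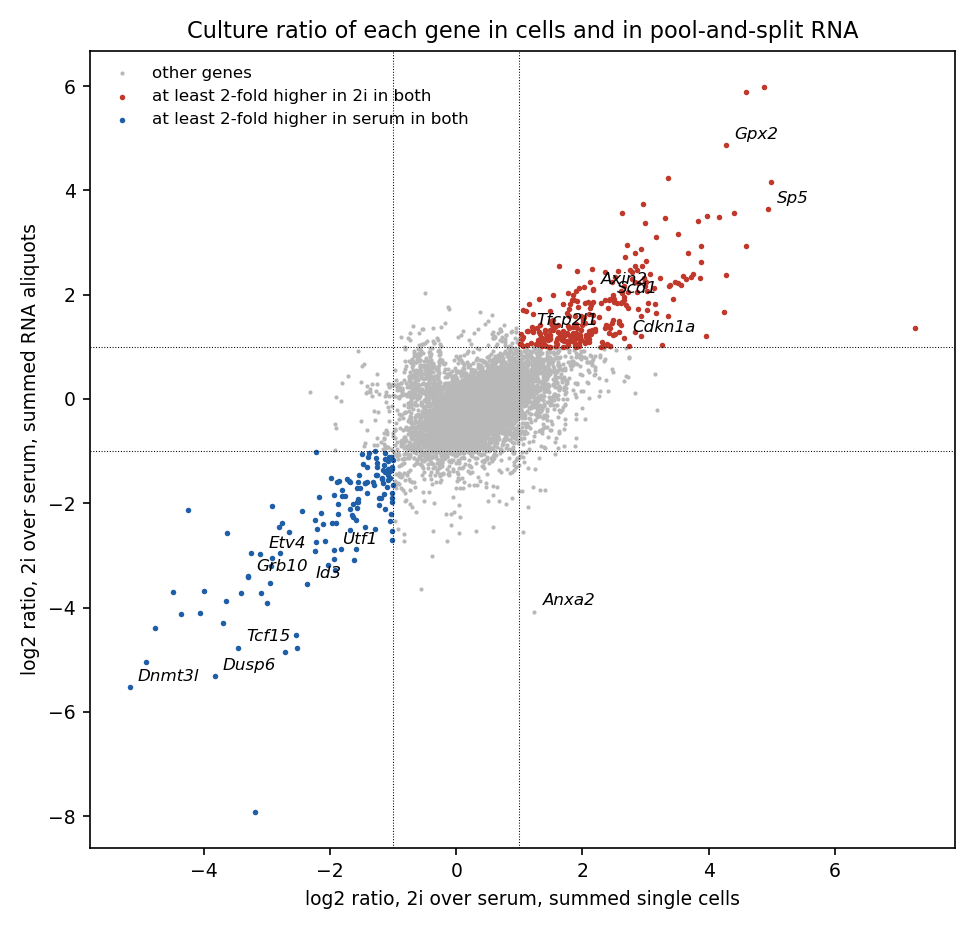
Log2 ratio of each of 7132 genes, 2i over serum, in summed single cells (x axis) and in summed RNA aliquots (y axis). The 268 genes in red were at least 2-fold higher in 2i in both materials and the 132 in blue at least 2-fold higher in serum in both, with dotted lines at 2-fold.

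Among the genes higher in 2i with the largest ratios, Gpx2, a glutathione peroxidase (chromosome 12, 76792333 to 76795554, GRCm38), had a log2 ratio of 4.28 (3.76 to 4.85) in cells and 4.87 (4.43 to 5.35) in aliquots. Fetub, which encodes the plasma protein fetuin B, had 3.98 (3.02 to 5.13) and 3.50 (2.84 to 4.24). In the other 5, 36.4% to 61.0% of the values above 0 were not whole UMI numbers, which makes their ratios uncertain. They were Gm9376 (4.88 in cells and 5.98 in aliquots), the homeobox gene Crxos1 (4.60 and 5.88), the X-linked Xlr3c (5.0 and 4.16) and the alpha-tubulin genes Tuba3a (4.17 and 3.49) and Tuba3b (4.41 and 3.57). A further 31 genes with at least 50 transcripts in 2i in both materials were listed at 0 in every serum column. Dppa3, a gene of naive stem cells and germ cells (chromosome 6, 122626410 to 122630272), led them with 555 transcripts in 2i cells and 1339 in 2i aliquots. Spic (124 and 186), Xlr3b (134 and 185), Gpx2-ps1 (152 and 184), Grin1 (136 and 167), Xlr4a (109 and 163), Bhmt (91 and 160) and the Wnt-responsive transcription factor Lef1 (89 and 168) followed, with transcripts in 2i cells and 2i aliquots in parentheses. Of these Xlr3b, Gpx2-ps1 and Xlr4a are uncertain, with 38.9% to 61.9% of their values not whole. No ratio is given for them, because every gene listed in a medium had values in at least 2 columns of both materials there, so that a 0 can stand for a value under a detection limit.

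On the serum side Dnmt3l lies on chromosome 10, 78041947 to 78063622, and was followed by Basp1, a membrane-bound signalling protein, at -4.92 (-5.62 to -4.29) in cells and -5.05 (-5.54 to -4.59) in aliquots. The imprinted gene Peg10 was at -4.78 (-5.75 to -3.95) and -4.39 (-5.36 to -3.56). Phlda1 was at -4.36 and -4.13, the actin-binding Cotl1 at -4.06 and -4.10, the transcription factor Tcfl5 at -4.49 and -3.71, and 1190005I06Rik at -3.71 and -4.29. Dusp6, the phosphatase that switches off ERK, was at -3.83 (-4.64 to -3.12) in cells and -5.31 (-6.33 to -4.46) in aliquots. Listed at 0 in every 2i column were 11 genes with at least 50 serum transcripts in both materials, among them the immediate early transcription factors Fos (234 transcripts in serum cells and 541 in serum aliquots) and Egr1 (169 and 310) and the receptor kinase inhibitor Spry4 (147 and 341). Col4a1, a basement membrane collagen, had 118 transcripts in serum cells and 944 in serum aliquots. Eras (105 and 194), Porcn (95 and 153), Bdh2 (62 and 108) and Htra1 (57 and 192) were also listed at 0 in 2i. Transcripts of fibroblast marker genes made up 0.161% of the serum aliquots and 0.00796% of the serum cells, against 0.00600% of the 2i aliquots and 0.00536% of the 2i cells, so ratios in aliquots include RNA that the serum cells did not hold.

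The gene lists placed these single genes in their pathways. The ERK target list had a median log2 ratio of -2.12 in cells and -1.93 in aliquots over 8 measured members, below all 10000 random lists of equal size and expression in both materials. At least 2-fold higher in serum in both were 5 of the 8, including Etv4 (-3.11 and -2.98), Spry2 (-1.42 and -1.59, uncertain with 53.2% of values not whole) and Junb (-2.22 and -2.74), and 4 more members were listed at 0 in 2i. Ccnd1 (1.67 and 0.37) and Etv5 (0.90 and 0.52) went the other way, higher in 2i in both. The Wnt target list had a median of 1.80 in cells and 1.54 in aliquots over 5 members, at percentiles 99.98 and 99.99 of the random lists, and 4 more members were listed at 0 in serum and 1, Nkd1, at 0 in 2i. Axin2, the feedback inhibitor of the pathway, was at 2.16 (1.65 to 2.71) and 2.09 (1.70 to 2.49), and Notum, which removes the lipid of Wnt proteins, at 2.10 and 1.30, while Lgr5, with no whole UMI numbers, was at -0.36 and 1.07, and at 0.15 and -0.80 in the blocks of cells. All 22 measured genes of sterol and fatty acid synthesis were higher in 2i cells and 15 were higher in 2i aliquots, with a median of 0.57 and 0.77 and percentile 100 in both. The desaturases Scd1 (2.42 and 1.91) and Scd2 (1.92 and 1.21) and the sterol sensor partner Insig1 (1.33 and 1.16) were at least 2-fold higher in both. All of these list medians kept their sign under every scaling tried.

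Genes of the primed epiblast had a median of -2.13 in cells and -1.34 in aliquots over 5 members, with percentiles 0 and 0.02, while 3 more were listed at 0 in 2i and 1 in serum. Tcf15 was at -3.46 (-4.27 to -2.74) and -4.77 (-5.44 to -4.17), the de novo methyltransferase Dnmt3a at -1.87 and -1.58, and Sox4 at -1.82 and -2.87. The imprinted genes had a median of -1.71 and -1.21 over 10 members, with percentile 0 in both, and 6 were at least 2-fold higher in serum in both, including Grb10 (-3.31 and -3.42), Snrpn (-1.77 and -1.86, uncertain with 49.1% of values not whole), Phlda2 (-1.74 and -1.54) and Mest (-1.07 and -1.36). Plagl1 was at least 2-fold higher in 2i in both (1.15 and 1.83), and 4 of the 10 imprinted genes were higher in 2i cells. DNA methylation genes had a median of -1.05 and -0.33 over 9 members, with percentiles 0 and 2.54, led by Dnmt3l, Dnmt3a and Tet2 (-1.98 and -1.51). Of the 9, 3 were higher in 2i cells and 2 in 2i aliquots. Uhrf1 (1.30 and 0.64) and Dnmt1 (0.58 and 0.47) were higher in 2i in both materials. The BMP and TGF-beta targets had a median of -0.77 and -1.56 over 4 members, with percentiles 0.77 and 0, and 1 member was higher in 2i in each material. Of them Id3, a BMP-induced inhibitor of differentiation, was at least 2-fold higher in serum in both, at -2.36 and -3.55. The stress and immediate early list was lower in 2i, with a median of -0.45 and -0.57 and percentiles 1.22 and 0.01, and 5 more members were listed at 0 in 2i and 1 in serum. Its members included Ier2 (-1.05 and -1.52) and Gadd45a (-2.95 and -3.21) on the serum side and Gadd45b (1.01 and 1.05) on the 2i side, the last under 2-fold in cells (0.71) after median-of-ratios scaling. The cell cycle inhibitor and p53 target Cdkn1a was at 2.66 (2.40 to 2.93) in cells and 1.16 (1.04 to 1.29) in aliquots, higher in 2i, while the other 10 measured p53 targets were not 2-fold apart in both materials.

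**Figure D2:**
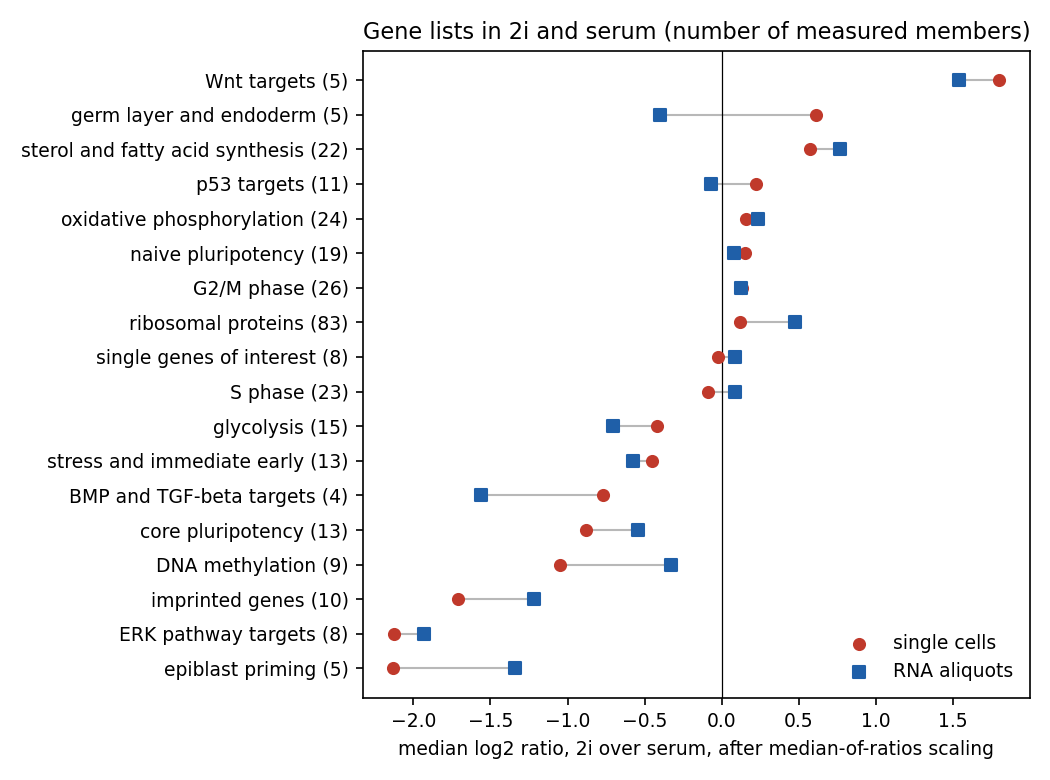
Median log2 ratio, 2i over serum, of the members of each gene list after median-of-ratios scaling, in single cells (red circles) and RNA aliquots (blue squares), with the number of measured members in parentheses. Wnt targets lie highest, at 1.80 and 1.54, and ERK targets and epiblast priming genes lie lowest, at -2.12 and -2.13 in cells.

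Pluripotency genes went both ways, and the direction of Pou5f1, Klf4 and Sox2 depended on block or scaling. Pou5f1, the central pluripotency factor Oct4, had 3571 transcripts in 2i cells and 3287 in serum cells, a log2 ratio of -0.05 (-0.12 to 0.02), and -0.14 (-0.20 to -0.08) in aliquots. Sox2 was at 0.10 (-0.02 to 0.22) and 0.03 (-0.06 to 0.12), and Klf4 at -0.05 (-0.18 to 0.07) and -0.60 (-0.69 to -0.51). In cells, columns 1 to 40 and columns 41 to 80 gave 0.32 and -0.43 for Pou5f1, -0.55 and 0.21 for Klf4, and 0.07 and 0.05 for Sox2. Median-of-ratios scaling put Pou5f1 at -0.36 in cells and 0.09 in aliquots, Klf4 at -0.36 in both, and Sox2 at -0.20 and 0.26. The direction in cells is thus not settled for Pou5f1, Klf4 or Sox2. Zfp42, known as Rex1, was higher in serum at -0.57 (-0.67 to -0.47) and -0.66 (-0.73 to -0.59), and so in each block of both materials. Esrrb went opposite ways as shares of all transcripts, with 0.46 (0.29 to 0.63) in cells and -0.44 (-0.57 to -0.32) in aliquots, and kept these signs in both blocks. Median-of-ratios scaling left 0.15 in cells and -0.21 in aliquots. As shares, columns 41 to 80 gave 0.19 and -0.22, each smaller in size than the shift by that scaling. The opposite directions of Esrrb are thus not settled. Nanog had only 15 to 24 summed transcripts per group, and its intervals, -0.48 to 1.54 in cells and -1.34 to 0.61 in aliquots, could not place it, with 2.69 and -0.55 in the blocks of cells. It is also uncertain, with 31.6% of its values not whole. The naive list had a median of 0.15 in cells and 0.08 in aliquots, and the latter changed sign without this scaling (-0.16 as shares of all transcripts). Tfcp2l1 (1.14 and 1.30) and Nr5a2 (1.05 and 1.20) were at least 2-fold higher in 2i as shares of all transcripts, but under 2-fold in cells after median-of-ratios scaling (0.84 and 0.75). Nr0b1 (-1.88 and -2.02) and Tet2 were at least 2-fold higher in serum. The core list was lower in 2i, with a median of -0.88 and -0.54 and percentile 0.01 in both, through Utf1 (-1.95 and -2.90), Lin28a (-2.25 and -2.91), Dppa2 (-2.11 and -2.40) and L1td1 (-1.17 and -1.51). Metabolic lists other than sterol synthesis were closer to 0. Oxidative phosphorylation had 0.16 in cells and 0.23 in aliquots, turning to -0.0021 in aliquots with equal weights per column, and glycolysis -0.42 and -0.71, turning to 0.0082 in cells under spike-in scaling. Of the glycolysis list Pdk1 (-1.09 and -1.55, uncertain with 93.0% of values not whole) was at least 2-fold higher in serum in both, though at -0.87 in columns 1 to 40 of cells. Of the S phase list Ccne1 (-1.56 and -1.58) was so too. The medians of the S phase list (-0.09 and 0.09) and of 8 single genes followed for other reasons (-0.03 and 0.09) changed sign with the scaling, and the G2/M list (0.13 and 0.13) did so in aliquots. Ribosomal proteins, at 0.12 and 0.48, took 16.7% of transcripts in 2i cells and 12.6% in serum cells. The germ layer list had medians of opposite sign, 0.61 in cells and -0.40 in aliquots.

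The pool-and-split aliquots measured how far technical variation reached. Genes with a mean of 10 to 20 transcripts had a median squared coefficient of variation (CV2) of 0.153 over 2i aliquots and 0.167 over serum aliquots, where Poisson sampling would give 0.0757 and 0.0759. After thinning to a common total, the CV2 was 0.0909 and 0.0881. At a thinned mean of 1 to 2 transcripts the median Fano factor, the variance divided by the mean, was 1.07 in 2i aliquots and 1.03 in serum aliquots, close to the Poisson value of 1. At 100 to 500 transcripts it was 2.64 and 2.72. The 4 spike-ins with a mean of 100 to 500 had an unscaled CV2 of 0.0445 in 2i aliquots, 0.0359 in serum aliquots, 0.0896 in 2i cells and 0.0695 in serum cells. These values pool the column blocks, whose median spike-in totals were 662 and 1064 in 2i cells and 997 and 1388 in serum cells. Within the blocks the CV of the spike-in total was 17.9% and 18.2% over 2i cells and 17.3% and 18.5% over serum cells. Over the aliquots it was 17.1% and 18.2% in 2i and 17.1% and 18.5% in serum. The higher CV2 in cells thus cannot be read as more variation between tubes of cells. Across genes, the CV2 over aliquots in 2i and in serum had a rho of 0.818. CV2 falls as the mean rises, so genes with a like mean in both media add to this rho.

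**Figure D3:**
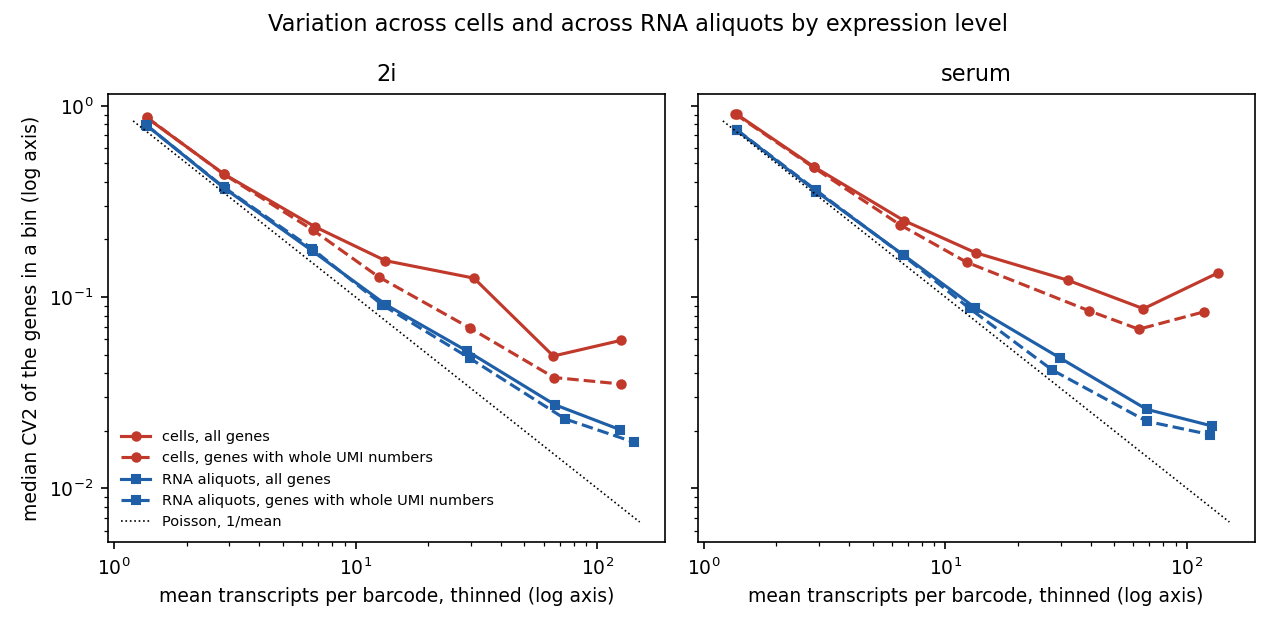
Median CV2 of genes by their mean number of transcripts per column, both on log axes, over cells (red) and RNA aliquots (blue) thinned to 33763 transcripts, in 2i (left) and serum (right). Solid lines are all genes, dashed lines genes with whole UMI numbers and the dotted line is the Poisson value, from which the aliquots depart less than the cells.

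The next comparison asked which genes varied between cells by more than this technical background. In both media the ribosomal RNA precursor Rn45s, at a lower level in cells than in aliquots, the hormone precursor Trh and the G2/M genes stood out. Fos and the stress transcription factor Atf4 did so in serum. Over genes with a thinned mean of at least 2 transcripts, the median CV2 was 0.303 over cells and 0.240 over aliquots in 2i (2205 genes) and 0.325 and 0.196 in serum (1990 genes). The CV2 was at least 2-fold higher in cells for 405 genes (18.4%) in 2i and for 812 genes (40.8%) in serum. The median excess, CV2 over cells minus CV2 over aliquots, was 0.0541 in 2i (0.0524 and 0.0417 in the blocks) and 0.120 in serum (0.129 and 0.0544). Among genes with whole UMI numbers it was 0.0256 and 0.0553, and the shares of genes at least 2-fold higher were 6.30% and 16.8%.

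Rn45s had a CV2 of 4.31 over 2i cells and 0.218 over aliquots, and of 1.67 and 0.357 in serum. Its thinned mean was 24.1 in 2i cells against 217 in 2i aliquots, and 83.5 against 196 in serum. The aliquots are thus not a background at a like level for this gene. Lrrc17, with 27.9% of its values not whole UMI numbers, had 2.45 over 2i cells and 0.189 over aliquots, and 1.47 and 0.240 in serum. The homeobox gene Rhox5 had 2.04 in 2i cells and 0.290 in aliquots, and Sdc4, a heparan sulfate proteoglycan, had 1.39 and 0.280. Trh had 1.35 and 0.563 in 2i and 2.44 and 0.345 in serum. Rn4.5s had 0.972 over 2i cells against 0.0720 over aliquots. Foxr1 (1.24 and 0.0998) and the histone gene Hist1h2aa (1.06 and 0.219) also led in 2i, with 98.5% and 96.2% of their values not whole UMI numbers. The mitotic kinase Plk1 (1.01 and 0.25), Igfbp2 (1.14 and 0.397) and the actin-sequestering Tmsb4x (0.888 and 0.200) completed the genes with whole UMI numbers in 2i. In serum, Fos had a CV2 of 1.55 over cells and 0.539 over aliquots, although its excess was 1.08 in columns 1 to 40 and 0.145 in columns 41 to 80. The amino acid transporter subunit Slc7a5 had 1.09 and 0.208, but its excess turned to -0.0345 when only genes with whole UMI numbers were thinned. Atf4 had 0.999 and 0.145, Arl6ip1 1.06 and 0.245, the thioredoxin inhibitor Txnip 1.34 and 0.456 and the intracellular cation channel Tmem38b 1.56 and 0.403.

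Among the lists, the G2/M genes had a median excess of 0.240 in 2i (percentile 100) and 0.222 in serum (percentile 98.5), and the sterol and fatty acid genes 0.162 (percentile 98.8) and 0.464 (percentile 99.98). S phase genes had 0.115 in 2i (percentile 97.4) and 0.145 in serum (percentile 58.9). The ERK targets in serum had 0.519 over 6 members (percentile 99.7) and DNA methylation genes 0.461 over 7 (percentile 99.8). The p53 targets had 0.230 in 2i over 5 members and 0.438 in serum over 3, at percentiles 99.1 and 98.3. The random lists were matched on mean expression, not on the gap between the means of cells and aliquots. A lower mean in cells adds counting noise to the excess. In serum the thinned mean of the p53 target Ccng1 was 2.72 in cells and 6.34 in aliquots. For the ERK target Ccnd1 it was 2.48 and 7.34, but 3.15 and 2.91 for Spry2. The part of this gap in the percentiles was not tested. Ribosomal protein genes lay lowest, with 0.0149 in 2i and 0.0455 in serum (percentiles 0 and 0.97).

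The third comparison asked whether cells in serum were more variable than cells in 2i, gene by gene. The excess CV2 was higher in serum for 68.6% of the 1812 genes measured in all 4 groups, with a median difference of 0.0532, serum minus 2i. Part of it came from the aliquots, since the median CV2 of these genes was 0.263 over 2i cells and 0.302 over serum cells, but 0.200 over 2i aliquots and 0.181 over serum aliquots. Within columns 1 to 40 the median difference was 0.0594 (68.4% of genes), and within columns 41 to 80 it was 0.00809 (53.5%). The higher excess in serum thus held in the first block, and the difference was near 0 in the second. Among genes with whole UMI numbers, thinned to their own common total of 15712, the median difference was 0.0240, against 0.0854 for the same genes thinned with all others. Thinned with all others, these 1079 genes had a median mean of 4.2 in serum cells and 5.9 in serum aliquots. In 2i it was 5.0 in both materials. Poisson sampling adds 1 over the mean to CV2, so this gap alone raises the excess in serum. Its part in the difference was not tested and may be most of it, so how much is variation between cells stays unknown. Thinned by themselves, these genes had a median mean of 4.6 in both serum materials, and there the difference was the 0.0240 given above. Atf4 (0.698), Arl6ip1 (0.578), Timm17a (0.520), Pbrm1 (0.576) and Pgls (0.415) had a higher excess in serum in both blocks, with the difference over all columns in parentheses. Trh (1.31) did so too, with 0.106 in columns 1 to 40 and 0.764 in columns 41 to 80. For Pbrm1 the CV2 over 2i aliquots (0.601) was above that over 2i cells (0.349), which adds to its difference. Unequal thinned means add counting noise to some of these differences. Pgls had a mean of 2.11 in serum cells and 3.50 in serum aliquots, against 3.19 and 2.47 in 2i. Timm17a had 2.30 and 5.04, against 2.53 and 3.27, and Pbrm1 2.48 and 2.96, against 2.93 and 2.0. Slc7a5 was at 0.75 over all columns but at -0.147 in columns 1 to 40 and at -0.459 among genes with whole UMI numbers. Without any scaling Arl6ip1 turned to -0.0331. Hmgcs1, the HMG-CoA synthase of the sterol pathway, was at 0.516, with 0.977 in columns 1 to 40 and 0.0564 in columns 41 to 80. Ogfrl1, Ahdc1 and Gas7 ranked high as well (1.52, 2.22 and 2.58), with a CV2 over the 2i aliquots of 4.44, 3.15 and 1.92 and with 48.7% to 75.3% of their values not whole. A second thinning seed turned Ogfrl1 to -0.499.

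Genes with a higher excess in 2i were fewer. Rn45s (-2.78), Lrrc17 (-1.04), Rbmxl2 (-0.441), Igfbp2 (-0.370), Tmsb4x (-0.356), the ubiquitin-conjugating enzyme Ube2s (-0.338) and Esf1 (-0.234) kept that direction in both blocks. So did Hist1h2aa (-0.622), Bloc1s3 (-0.641), Gm10636 (-0.507), Zfp959 (-0.635) and Marf1 (-1.28), whose values were 39.7% to 100% not whole, although Hist1h2aa turned to 0.234 and Zfp959 to 0.0491 without scaling. Ankrd11 (-0.613) and Ddt (-0.465) had a CV2 of 1.22 and 0.706 over the serum aliquots, above the 0.721 and 0.482 over serum cells, so their excess in serum was below 0. The direction of Ddt was not stable, with 0.035 to 0.261 under 6 of the alternatives, a second seed among them. The CV2 over serum aliquots was also above that over serum cells for Rbmxl2, Esf1, Ube2s, Bloc1s3, Gm10636, Zfp959 and Marf1. For Tmsb4x the thinned mean was 2.35 in 2i cells and 5.56 in 2i aliquots, against 17.3 and 40.98 in serum. Counting noise thus raises its excess more in 2i than in serum and makes up part of its difference. Ube2s had means of 4.28 and 7.15 in 2i, against 4.93 and 3.68 in serum, which also makes its difference larger in size. By list, all 9 naive pluripotency genes had a higher excess in serum, with a median difference of 0.143 (percentile 97.2), 0.157 in columns 1 to 40 and 0.127 in columns 41 to 80. Jam2 (0.364) and Klf4 (0.307) led them. The thinned mean of Jam2 was 2.74 in serum cells and 3.68 in serum aliquots, against 5.40 and 3.99 in 2i, so counting noise adds to its difference. Of the sterol and fatty acid genes 6 of 7 were higher in serum, with a median of 0.391 (percentile 99.97), 0.614 in columns 1 to 40 and 0.0564 in columns 41 to 80, led by Fdps (0.571). Oxidative phosphorylation had 0.123 (percentile 99.3) over 23 genes, with 0.130 and 0.00037 in the blocks. Ribosomal proteins had 0.0334 over 82 genes, with 0.0453 and 0.0034. DNA methylation genes had 0.239 over 4 genes, with 0.267 and -0.00153, since Tet1 (-0.161) and Mbd3 (-0.201) were lower in serum in columns 41 to 80. Among ERK targets and DNA methylation genes, the cyclin gene Ccnd1 (0.532), Etv5 (0.325), Uhrf1 (0.466) and Dnmt1 (0.391) were higher in serum in both blocks. Counting noise adds to these differences, since each had a lower thinned mean in serum cells than in serum aliquots. For Ccnd1 the means were 2.48 and 7.34, against 7.44 and 9.72 in 2i. G2/M genes had 0.0414 (percentile 32.6), with 0.0282 and 0.0322 in the blocks, and S phase genes 0.0443 (percentile 22.5), with 0.0596 and -0.0384. The sign also turned between blocks for core pluripotency genes (0.0784 over all columns, 0.106 and -0.0229) and p53 targets (-0.0863, -0.0519 and 0.212), but not for glycolysis (0.0904, 0.0717 and 0.0621). Pou5f1 had a CV2 of 0.0558 over 2i cells and 0.173 over serum cells, with 0.0370 and 0.0500 over the aliquots, and a difference of 0.0769 in columns 1 to 40 and of -0.0239 in columns 41 to 80.

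**Figure D4:**
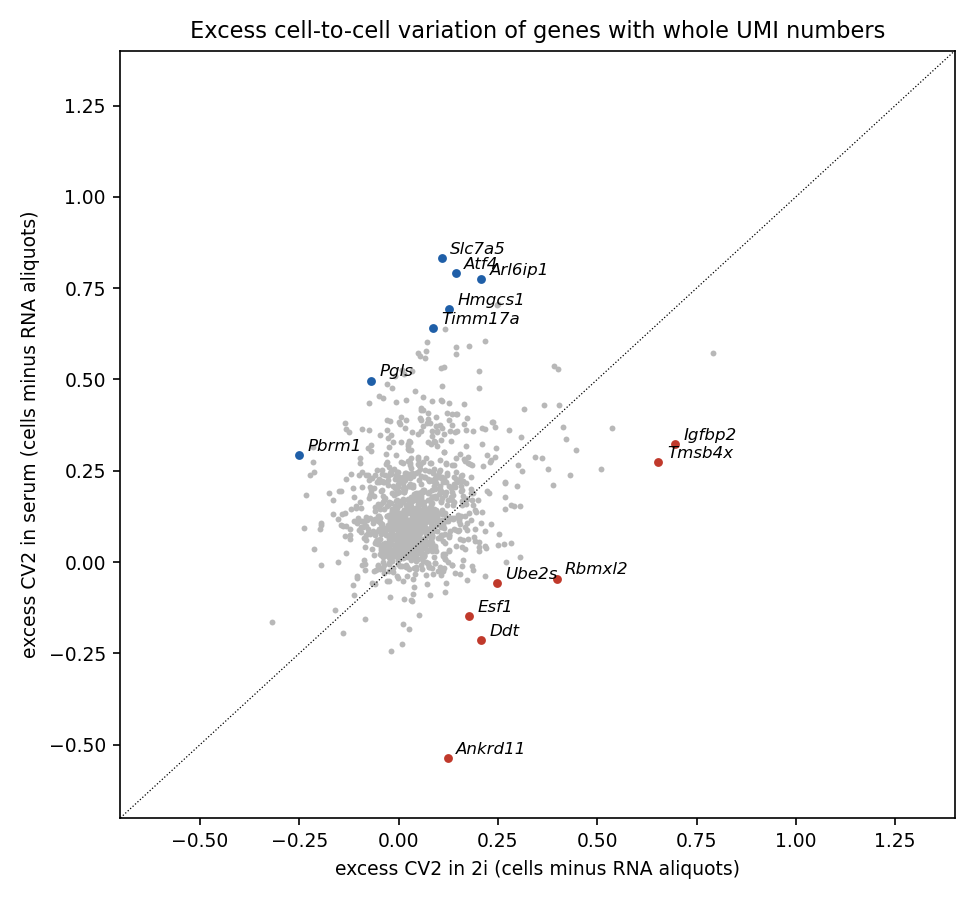
Excess CV2 (cells minus RNA aliquots) of 1181 genes with whole UMI numbers in 2i (x axis) and serum (y axis), each after leaving out the gene's highest column, with the named genes in blue (higher in serum) and red (higher in 2i). More genes lie above the dotted line of equality than below it, and Rn45s and Trh lie outside the axes.

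The last comparison asked whether genes of a list rose and fell together across cells. G2/M genes had a median pairwise rho of 0.369 over 2i cells and 0.171 over serum cells, against -0.0212 and 0.00891 over the aliquots. Sterol and fatty acid genes had 0.149 over 2i cells and 0.422 over serum cells, against 0.0294 and 0.0165. Averaged within the blocks, the G2/M genes had 0.330 and 0.175 and the sterol genes 0.187 and 0.356. S phase genes had 0.229 over 2i cells and 0.0693 over serum cells (0.211 and 0.0719 within the blocks). Ribosomal protein genes had 0.302 and 0.432 over cells (0.283 and 0.353), with 0.151 and 0.0930 over aliquots (0.107 and 0.0823). The naive pluripotency genes had 0.101 and 0.161 over cells (0.103 and 0.131) and 0.0618 and 0.0174 over aliquots (0.0438 and -0.0197). Core pluripotency genes, DNA methylation genes and glycolysis genes had 0.174, 0.211 and 0.211 over serum cells, which came down to 0.0711, 0.0879 and 0.0789 within the blocks.

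**Figure D5:**
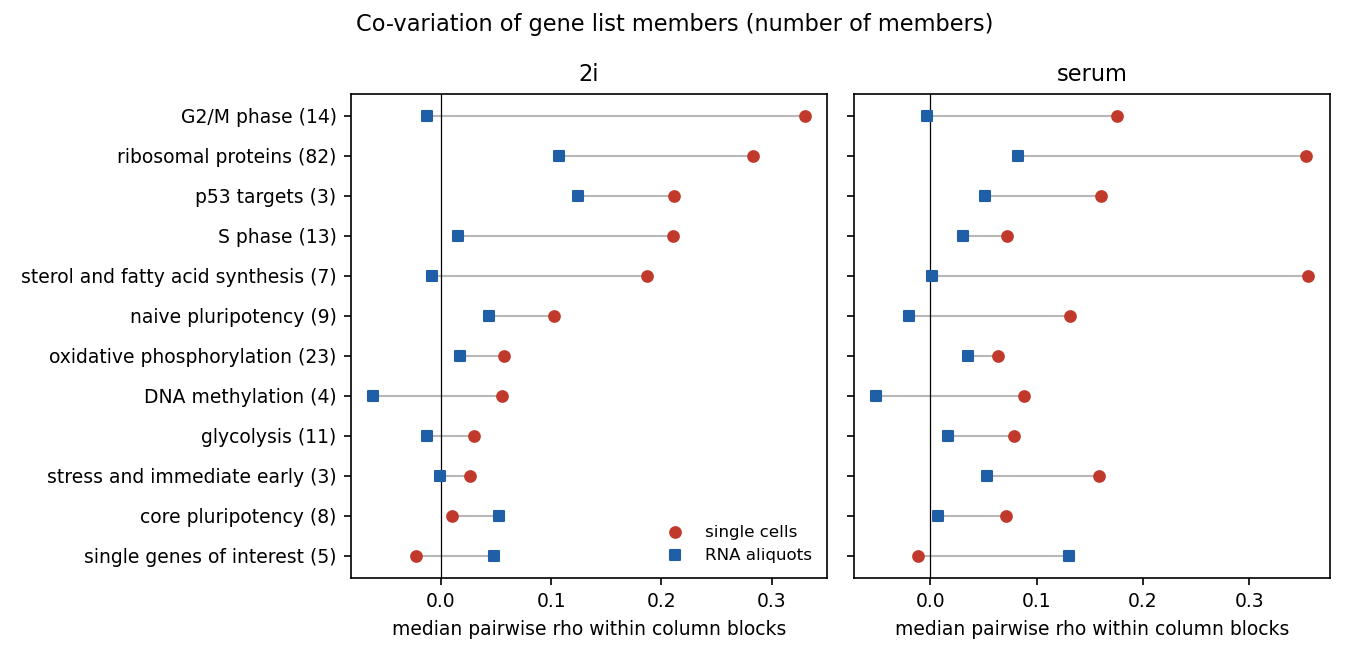
Median pairwise Spearman rho among the members of each gene list, averaged over the 2 column blocks, over single cells (red circles) and RNA aliquots (blue squares) in 2i (left) and serum (right), with the number of members in parentheses. G2/M genes reach 0.330 in 2i cells and sterol and fatty acid genes 0.356 in serum cells, while both lie near 0 in the aliquots.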

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

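All tests in this part were chosen after the data were seen, with the bounds for shared reads and composition written before their own values were computed, and the bound for column blocks, under which a fall in either block would have counted, split by block afterwards. Of the genes at least 2-fold apart between media in both materials, 16 had opposite signs in cells and aliquots, higher in 2i cells and lower in 2i aliquots, with counting intervals that exclude 0 in both. The difference between materials was not tested, since each is 1 pooled sample. The log2 ratio, 2i over serum, in cells was 1.23 for Anxa2, 1.11 for E030030I06Rik, 1.04 for Fst, 1.05 for Gm13315, 1.01 for Gm8096, 1.41 for Maged2, 1.25 for Map7d1 and 1.06 for Maz. It was 1.32 for Mettl21e, 1.56 for Mir686, 1.04 for Nt5c3b, 1.07 for Reep5, 1.22 for S100a11, 1.31 for Slc24a5, 1.14 for Timp1 and 1.14 for Tpm4. In aliquots it ranged from -4.08 for Anxa2 to -1.01 for Nt5c3b. Several of these, such as Anxa2, S100a11, Timp1 and Tpm4, are abundant in fibroblasts and other adherent cells.

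A shift in composition of the serum cells stays open. All 16 kept opposite signs when shares were taken among genes with whole UMI numbers, but that moves every gene of a material alike and by less than the 2-fold used to choose them, so no sign could turn, and only 3 stayed at least 2-fold apart in both. RNA of the feeder fibroblasts is a candidate source of the aliquot side, since the cells lysed for the aliquots came from cultures on fibroblasts while single cells were picked by eye. All 14 fibroblast markers with at least 50 serum transcripts were at least 2-fold higher in serum aliquots than in serum cells, with a median log2 ratio of 3.74, above all matched random lists. The feeders leave open why these genes were higher in 2i cells than in serum cells, and cells that differentiate in serum were not tested as another source.

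The second pattern, the higher excess variation in serum, was 0.0594 within columns 1 to 40 and 0.00809 within columns 41 to 80, so a difference between the blocks cannot account for it in the first block and leaves almost nothing to explain in the second. Both blocks were small. After thinning, the first kept 20 cells in 2i and 28 in serum, and the second kept 37 and 18. Genes with whole UMI numbers, thinned by themselves to 15712 transcripts (60 cells in 2i and 41 in serum), had a median difference of 0.0240, just above the bound of 0.02, but 0.0182 and 0.0105 within the blocks, so the bound did not decide. The same 1079 genes had 0.0854 when thinned together with all others. Their median mean was then 4.2 transcripts in serum cells and 5.9 in serum aliquots, and 5.0 in both materials of 2i. Thinned by themselves they had 4.6 in serum cells, 4.6 in serum aliquots, 4.3 in 2i cells and 4.2 in 2i aliquots. By these medians, counting noise raised the serum excess in the joint thinning and hardly at all in the other. Variation in fractional values may also make up part of the difference, and the cells kept changed as well. These cannot be told apart here. The share of transcripts from genes with mostly fractional values had an SD of 7.91 percentage points over serum cells and 6.0 over 2i cells, against 3.07 and 2.72 over the aliquots. The effect of the medium cannot be told apart from that of feeders, passaging enzyme and culture, since the columns tell apart only 1 culture per medium and the number of cultures is not given in the sources used here.

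The third pattern is the set of genes listed at 0 in a whole medium. A detection filter applied by the authors per medium and true absence cannot be told apart. That 0 genes were at 0 in only 1 of the 2 materials of a medium is the observation that prompted the idea of a filter and so cannot test it. Absence could not be tested either, since 0 listed genes had a value in fewer than 2 columns of a group and the low end of the distribution is thus not in the table.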

How the results depend on the processing

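No paired analysis was possible because the columns carry no library or lane number. Whole-UMI genes and column blocks were alternatives chosen after seeing the data; the cause of a change was not tested unless stated. The counts of genes at least 2-fold higher in 2i and in serum stayed within 1.5 times of 268 and 132 under median-of-ratios and TMM scaling, equal weights, all columns, whole-UMI genes, genes listed at 0 kept at a floor of 3 transcripts and without each gene's highest column. Spike-in scaling gave 439 in 2i. A minimum of 3 transcripts gave 317 in serum and a minimum of 200, which leaves fewer genes, gave 82 and 36. Columns 1 to 40 gave 113 in 2i and columns 41 to 80 gave 71 in serum. None of the culture ratios followed here, those of the genes with the largest ratios and of list members at least 2-fold apart in both materials, changed sign. Ccnd1, Etv5, Lgr5, Plagl1 and the 6 pluripotency genes were followed only by block, median-gene and whole-UMI scaling, which turned several of them. No cell had over 1% fibroblast transcripts, so leaving such cells out removed none and tests nothing.

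The noise values depended on how depth was removed. The median excess in 2i and serum was 0.188 and 0.321 scaled to the median total, 0.287 and 0.430 unscaled, 0.240 and 0.361 scaled to spike-ins, and 0.0256 and 0.0553 for whole-UMI genes. Thinning to the 25th percentile gave 0.0326 in 2i, and columns 41 to 80 gave 0.0544 in serum. The share of genes with CV2 at least 2-fold higher in cells was 51.5% and 89.6% scaled, 67.4% and 89.7% unscaled, 64.1% and 92.5% with spike-ins, 6.30% and 16.8% for whole-UMI genes, and 32.0% in 2i at a mean of at least 5. The median difference, serum minus 2i, was above 0 under every alternative: 0.0949 scaled, 0.121 unscaled, 0.125 with spike-ins, 0.100 at a mean of at least 1, 0.0275 at a mean of at least 5, 0.0240 for whole-UMI genes and 0.00809 in columns 41 to 80. For whole-UMI genes it was 0.0182 and 0.0105 within the blocks. No alternative matched the means of cells and aliquots gene by gene, so the shared sign is not independent support. The aliquots' CV2 at a mean of 10 to 20 was 0.0909 (2i) and 0.0881 (serum) thinned, and 0.0949 and 0.0704 scaled. With all columns the CV of totals was 89.2% over serum cells and 71.9% over serum aliquots, because nearly empty columns enter.

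The difference, serum minus 2i, changed sign for single genes. For Ddt it was 0.245 at the 25th percentile, 0.156 scaled, 0.114 unscaled, 0.035 with a second seed, 0.184 with spike-ins and 0.261 for whole-UMI genes. For Slc7a5 it was -0.459 for whole-UMI genes, where its excess in serum was -0.0345, and -0.147 in columns 1 to 40. Unscaled, it was -0.0331 for Arl6ip1, 0.234 for Hist1h2aa and 0.0491 for Zfp959, and with a second seed -0.499 for Ogfrl1. Leaving out each gene's highest column kept the sign but made the difference smaller in size for some. It was then 0.958 for Gas7, 1.34 for Ahdc1, 0.824 for Trh and -0.607 for Marf1. Low counts limit genes such as Nanog, and noise was compared between media for 1812 genes only.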

Other observations

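The H2A genes as a set and both tests on them were chosen after the data were seen. The histone H2A genes moved as 1 signal. Among the 16 of them above the mean floor, the median pairwise rho was 0.973 over 2i cells and 0.940 over serum cells, and 0.687 and 0.488 over the aliquots, with a median of 99.8% of values not whole UMI numbers. Their summed share ranged from 0.0415% to 4.59% over 2i cells and from 0.0444% to 2.96% over serum cells, and only from 1.12% to 3.32% and from 0.524% to 1.57% over the aliquots. With thinned values the rho in cells exceeded that in aliquots by at least 0.286, but with values scaled to the median total it was 0.990 and 0.985 over cells against 0.869 and 0.812 over aliquots. Sharing of reads between near-identical copies may still be the reason that so many genes move alike, because a single varying gene whose reads are spread over its copies would raise all of them in cells. The bound on this difference therefore could not decide. Whether cells in S phase hold more H2A transcripts stays open. The rho of summed H2A with the summed S phase list was 0.159 over 2i cells and 0.101 over serum cells, above that over the aliquots by 0.433 in 2i and 0.351 in serum. Averaged within the column blocks the rho was 0.101 and 0.0862, above the aliquots by 0.200 in 2i but by -0.00249 in serum. With the G2/M list the rho was -0.180 over 2i cells and -0.342 over serum cells.

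A pair of genes outside the rule for named genes stood far from the others in the plot of culture ratios and were chosen after their values were seen. Ly6a, the stem cell antigen Sca-1, had 526 transcripts in 2i cells and 3 in serum cells (log2 ratio 7.28, interval 5.73 to 9.56), but 584 in 2i aliquots and 217 in serum aliquots. S100a6 had 73 transcripts in serum cells and 4838 in serum aliquots, against 9 and 21 in 2i.

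Of 13 genes of the cleavage-stage programme 5 were in the table, and 4 of these, all Zscan4 copies, were listed at 0 in 2i, which a detection filter per medium would also give. The list took 0.00206% of transcripts in serum cells and 0.0149% in serum aliquots. The endoderm markers Gata4, Gata6, Sox17, Sox7, Foxa2, Pdgfra and Dab2 had 2 members in the table, with 6 transcripts in 2i cells and 28 in serum cells. The excess CV2 of genes in 2i and in serum had a rho of 0.157 across the 1812 genes. The CV2 over the aliquots had 0.818, but CV2 follows the mean of a gene, which the excess takes away in part. The 2 values are thus not like measures.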
